A study of Mus musculus with 23 samples.

How the data were processed

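RNA was measured in 23 libraries of cultured mouse forebrain cells, in 8 groups that follow the sample titles. The overexpression set held 11 libraries and the knockdown set 12, each in its own count table. Per the labels' protocols, total RNA was column-purified, 10 ng of it went into each library, and libraries were made with a strand-specific SMARTer kit. Per the submitters' processing notes, the authors used bcl2fastq and Salmon and the mouse genome build GRCm38. No version of these tools, no transcript set and no filter is given in the sources used here. The deposited tables hold expected counts, which are estimated counts per Ensembl gene as Salmon gives them, without further normalization as far as the values show. How transcripts were summed to genes is not given in the sources used here.

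Both tables list the same 34866 gene identifiers, of which 34652 were matched to the GENCODE M21 annotation of GRCm38. Of these, 21850 are protein-coding and 12300 are pseudogenes, among them 9081 processed pseudogenes, so reads shared between a gene and its near-identical copies could be split between them. This makes ribosomal protein and histone genes uncertain. Symbols that belong to several identifiers were left out of the named genes. All 23 count columns were matched to samples by the library names in the labels, and 0 columns were left over. Replicates were compared before averaging. None of the 22 pairs of libraries within a group held identical values, and their counts differed by 1.46 to 3.85 times sampling noise (chi-square per degree of freedom), so each was counted as its own sample. The labels do not say that replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

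Expected counts were rounded to whole numbers. Genes with low counts were removed by filterByExpr, which left 26682 genes in the overexpression table and 25654 in the knockdown table. Each table was fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, a term for the group and a term for the batch date that the labels give (16 or 21 July 2023). P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. The labels do not say what step the batch date refers to. All adjusted p-values for genes come from this test unless another tool is named. Standard errors of log2 changes are those implied by the F statistic. Levels are given as CPM, counts relative to the library total scaled by TMM factors, as mean and SD over the libraries of a group. Tests were run within a table only.

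The comparisons were the 3 factors against EGFP in each tissue, the 3 shRNA vectors against shControl in each tissue, the difference of these effects between tissues, and cortex against ganglionic eminence in each control group. Relations between comparisons were measured by Spearman's correlation across genes and by overlaps of called genes, each set against the overlap of independent lists with Fisher's exact test (two-sided, 16 overlaps adjusted together). No control library is shared by the comparisons set side by side, although both comparisons of a table share its batch term. Genes are not independent replicates.

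In each comparison 38 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, beside it, with an estimated correlation and with fry, which asks only whether a list's genes move, on balance, in the same direction. Adjustment ran over all lists of a comparison. The lists hold 679 distinct genes, 668 of which were found, and cover cell types and regions of the forebrain, temporal progenitor states, signalling and metabolic pathways, markers of other cell types and signs of RNA quality. The lists, the comparisons, the tests and most alternatives were fixed before the data were examined, and so was the rule for the genes named. That rule took the 3 targets, the 8 highest and 8 lowest called genes with a mean of at least 5 CPM and with no overlap between groups, up to 4 called members per list by lowest p, the 2 most abundant members of a list under discussion and the 10 overlap genes with the lowest larger p. Predicted-gene names were left out of the highest and lowest genes.

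Genes of the olfactory, vomeronasal and trace amine receptor, defensin and keratin-associated families served as a silent panel of 1586 genes. The 451 of them without repeated sequence, as judged by stretches of 21 bases present in at least 20 genes, gave each library a background per kilobase of transcript. That background was set against the counts of 8881 repeat-free coding genes. It was then subtracted from coding genes with at most 0.5% repeated sequence, and genes at least 2 times above it with at least 10 counts left were refitted (3283 in the overexpression table and 1297 in the knockdown table). Libraries were scaled for this either by TMM among the expressed genes or to the signal that remained after subtraction. Both analyses were added after the data had been seen, the TMM scaling second and after the calls under the signal scaling were known. Some other versions were tried while this was being set up and are not reported here. Genes whose GENCODE transcripts match an Alu consensus sequence were found with blastn (BLAST 2.17.0, e-value 0.001, word size 11, at least 30 bases and 80% identity), which gave 2050 genes. The consensus was typed from memory rather than taken from a sequence database, and this search was also added after the data had been seen.

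The alternatives were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), no filter on low counts, no batch term, only the groups compared, libraries of a single batch date, a replicate block, and each library left out in turn. The fit of the 21 July libraries between the EGFP groups was added after the data had been seen. Python 3.11.15 was used for tables and figures. Library totals ran from 4259924 to 6424513 counts in the overexpression table and from 2948321 to 4731084 in the knockdown table. The steps were tested on simulated counts drawn from each gene's mean over all libraries of a table, the real library sizes and the fitted dispersions, with 200 genes of at least 20 expected counts changed. Changes of 1.5, 2 and 4 times were recovered for 49.3, 74.6 and 97.0% of the changed genes in cortical neurospheres (8 false calls over 26081 genes). The corresponding shares were 65.7, 88.1 and 98.5% in neurospheres of the ganglionic eminence (12 over 26069). In the knockdown table they were 44.8, 91.0 and 100% in cortex (9 over 25237) and 49.3, 86.6 and 98.5% in the ganglionic eminence (11 over 25197). No simulated change was called in the wrong direction. Absolute sequence coverage, vector sequences and the reads themselves were not analysed here.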

Results

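To examine what the transcriptional regulators Phf21b, Zfp7 and Zfp57 do in the embryonic mouse forebrain, RNA was sequenced from cells given vectors that express all 3, or shRNA vectors directed against all 3. Phf21b encodes a PHD finger protein related to a subunit of histone demethylase complexes. Zfp57 encodes a KRAB zinc finger protein that keeps DNA methylation at imprinted regions, and Zfp7 encodes another zinc finger protein. The title of the series places the work in the study of how the timing of neuron subtype differentiation is controlled. For overexpression, neural stem and progenitor cells were taken from cerebral cortex at E12.5 or from the ganglionic eminence, the ventral source of inhibitory neurons, at E13.5. They grew as floating neurospheres with doxycycline-inducible lentiviral vectors for the 3 factors (3FOE) or for EGFP until day 5. For knockdown, primary cultures from both tissues at E11.5 carried 3 shRNA vectors (sh3F) or a control shRNA vector (shControl) until day 5 of differentiation. There were 2 cortical EGFP libraries and 3 libraries in each of the other 7 groups.

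Library totals ran from 4259924 to 6424513 counts in neurospheres and from 2948321 to 4731084 in primary cultures. Many counts fell on genes that brain cells are not known to express. The silent panel of receptor, defensin and keratin-associated genes took 4.91 to 8.35% of all counts, depending on the library. A background in proportion to transcript length, set by its repeat-free members, equalled 67.4% ± 4.5 (SD, n = 2) of the counts of repeat-free coding genes in cortical EGFP and 79.6% ± 4.1 (n = 3) in cortical 3FOE neurospheres. The same measure gave 32.5% ± 2.9 and 42.6% ± 2.5 in EGFP and 3FOE neurospheres of the ganglionic eminence. In primary cultures it was 85.3% ± 4.6 for cortical shControl, 87.8% ± 1.9 for cortical sh3F, 76.6% ± 1.8 for ganglionic eminence shControl and 85.4% ± 3.1 for ganglionic eminence sh3F (n = 3 each). Because this share differed between the groups compared, each comparison was repeated with the background subtracted, with libraries scaled by TMM or to the remaining signal. Relative to the fits without subtraction, these scalings moved the log2 changes of the refitted genes by a median of 0.153 and 0.617 for 3FOE in cortex, 0.268 and 0.365 for 3FOE in the ganglionic eminence, and 0.862 and 1.12 between the EGFP groups. In the same order they moved them by 0.0528 and 0.138 for sh3F in cortex, 0.088 and 0.696 for sh3F in the ganglionic eminence, and 0.0394 and 0.745 between the shControl groups. The tissue difference moved by -0.114 and 0.253 for 3FOE and by -0.0339 and -0.544 for sh3F. These shifts act on the refitted genes together, so a sign that turns with a scaling alone does not set a list or gene apart from the others. Medians with the background subtracted are over the refitted members of a list, 3283 genes being refitted in neurospheres and 1297 in primary cultures.

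**Figure D1:**
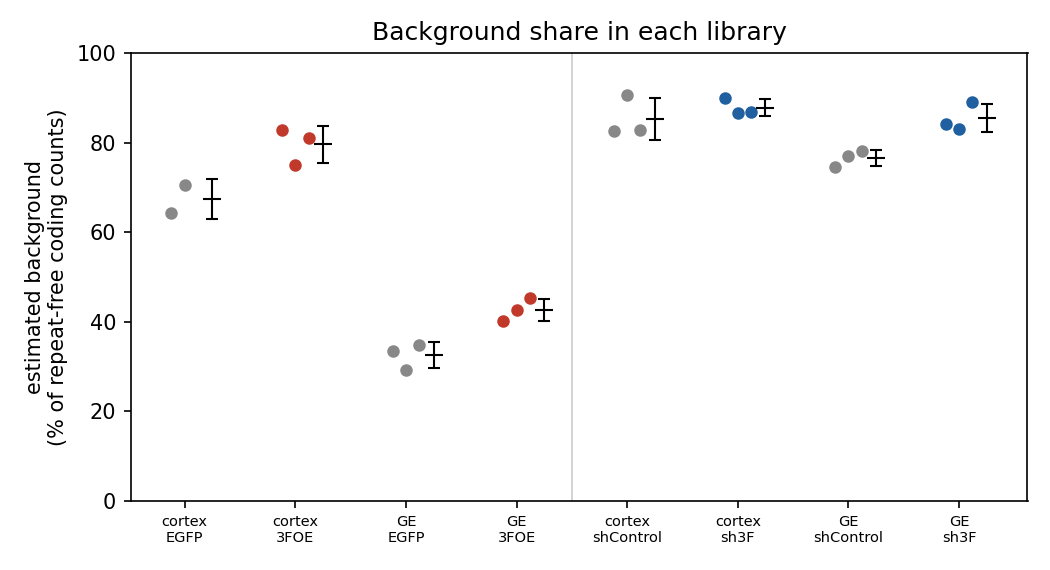
Estimated background as a percentage of the counts of repeat-free coding genes in each of the 23 libraries, with points for libraries and, beside them, the group mean with bars for its SD (GE, ganglionic eminence). Neurospheres of the ganglionic eminence lie lowest, with means of 32.5% (EGFP) and 42.6% (3FOE), and all primary cultures have group means of 76.6% or more.

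The 3 target genes were examined first in every library. Phf21b (ENSMUSG00000016624) lies on the minus strand of chromosome 15 at 84785381 to 84856049, Zfp7 (ENSMUSG00000033669) on the plus strand of chromosome 15 at 76879259 to 76892395, and Zfp57 (ENSMUSG00000036036) on the plus strand of chromosome 17 at 37001163 to 37010635 (GRCm38). In cortical neurospheres, 3FOE raised Phf21b from 21.5 ± 4.63 to 273 ± 14.6 CPM (log2 change 3.65 ± 0.151 SE, adjusted p = 1.34e-13). Zfp7 rose from 36.8 ± 3.17 to 334 ± 31.1 CPM (3.17 ± 0.14, adjusted p = 2.9e-13) and Zfp57 from 11.3 ± 1.34 to 196 ± 21.4 CPM (4.16 ± 0.181, adjusted p = 1.57e-11). In neurospheres of the ganglionic eminence the factors rose by 3.86 ± 0.123, 4.35 ± 0.128 and 4.92 ± 0.145 on the log2 scale, to 664 ± 109, 604 ± 93.9 and 607 ± 119 CPM. Every 3FOE library lay above every EGFP library for each factor.

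Measured changes with knockdown were far smaller. In the ganglionic eminence Phf21b fell from 29.2 ± 3.76 to 18.4 ± 3.08 CPM (log2 change -0.74 ± 0.158, adjusted p = 0.00157), and each sh3F library lay below each shControl library. Zfp57 fell from 23.1 ± 0.708 to 15.1 ± 2.49 CPM (-0.60 ± 0.176, adjusted p = 0.0347). That call was lost with DESeq2, within the 16 July libraries and without any of 5 of the 6 libraries (adjusted p up to 0.211). Zfp7 was at 42.4 ± 7.43 (sh3F) and 39.1 ± 2.94 CPM (shControl) in that tissue (0.08 ± 0.125, adjusted p = 0.84). In cortex no target passed, with log2 changes of -0.41, -0.12 and -0.22 for Phf21b, Zfp7 and Zfp57 (adjusted p = 0.302, 0.849 and 0.789). These transcripts lay close to the estimated background. In sh3F libraries Phf21b had 50 to 72 counts in cortex (background 62.2 to 75.5) and 48 to 66 in the ganglionic eminence (61.7 to 71.1). There Zfp57 had 38 to 62 (54.8 to 63.2), so these changes may understate the falls. A lowering of Zfp7 in either tissue, or of any target in cortex, was not detectable at this depth, so the groups are called cultures labelled sh3F.

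**Figure D2:**
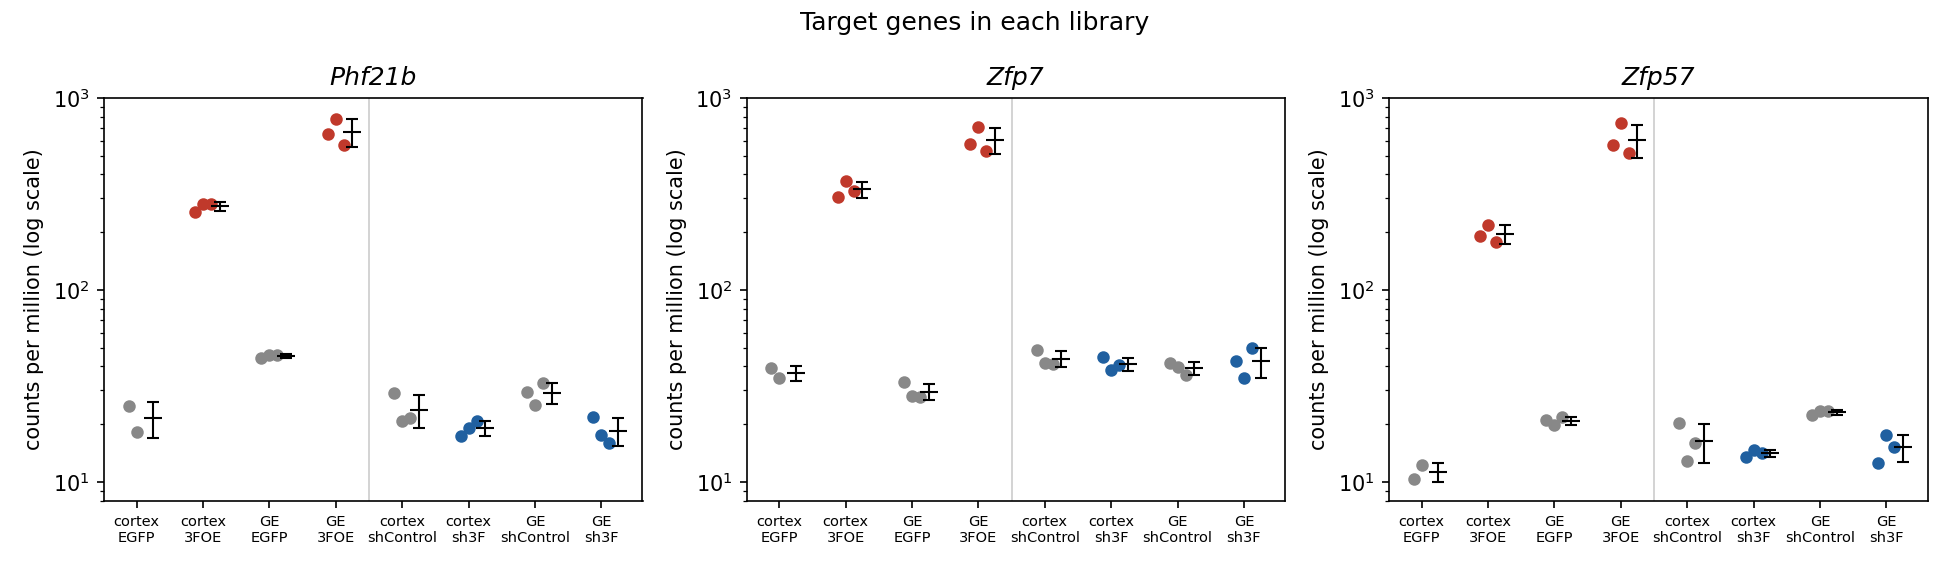
CPM of Phf21b, Zfp7 and Zfp57 in each library on a log axis, by group, with points for libraries and, beside them, the group mean with bars for its SD (GE, ganglionic eminence). All 3FOE libraries lie above all EGFP libraries, and in the ganglionic eminence the sh3F libraries lie below the shControl libraries for Phf21b (means of 18.4 and 29.2 CPM) and Zfp57 (15.1 and 23.1 CPM) but not for Zfp7 (42.4 and 39.1 CPM).

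To see what the raised factors did in cortical neurospheres, 3FOE was compared with EGFP (n = 3 and 2). Several regulators of the oligodendrocyte lineage fell. Olig1 and Olig2, transcription factors that specify this lineage, went from 75.1 ± 0.961 to 38.4 ± 8.65 CPM (log2 change -0.99 ± 0.141 SE, adjusted p = 0.000525) and from 89.3 ± 12.2 to 46.9 ± 6.81 CPM (-0.90 ± 0.118, adjusted p = 2.89e-05). Sox8, a related regulator of glial fate, fell by 0.97 ± 0.118 (adjusted p = 1.34e-05). In all, 14 genes rose and 141 fell. For every gene named with a passing p in this and the following comparisons of treated with control libraries, each treated library lay beyond each control library unless stated otherwise.

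In cortical 3FOE neurospheres, of 16 oligodendrocyte lineage genes measured, 5 fell over all genes tested and 9 when adjusted over the list alone (camera adjusted p = 4.71e-24, but adjusted p = 0.105 with an estimated correlation). The median of the 10 refitted members stayed below 0 under both background-subtracted scalings, but Olig1, Olig2 and Sox8 were called only under TMM scaling (log2 changes of -0.87, -0.75 and -0.81, against -0.42, -0.29 and -0.35 with signal scaling). Sox10, which drives myelin genes, fell by 0.89 ± 0.184 (adjusted p = 0.0225), and Gpr17, a receptor of immature oligodendrocytes, had a log2 change of -1.10 ± 0.236 that did not pass (adjusted p = 0.145). Of 15 radial glia markers, 2 fell over all genes and 9 when adjusted over the list alone (camera adjusted p = 4.1e-13, and adjusted p = 0.105 with an estimated correlation). They were the intermediate filament gene Vim (-0.66 ± 0.104, adjusted p = 0.000565), whose change became 0.03 with signal scaling, and the glutamate transporter gene Slc1a3 (-0.59 ± 0.103, adjusted p = 0.00361). Fabp7, the fatty acid binding protein of radial glia, was measured at 584 ± 129 against 1020 ± 45.1 CPM (adjusted p = 0.106).

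Late progenitor genes had 2 of 20 members lower, and 7 when adjusted over the list alone (camera adjusted p = 2.45e-07, adjusted p = 0.512 with an estimated correlation), although the median of 10 refitted members was positive with signal scaling. One was Pla2g7, a lipid-cleaving enzyme of glia (-0.86 ± 0.116, adjusted p = 4.18e-05). Among 18 astrocyte genes 1 fell, and 7 when adjusted over the list alone (camera adjusted p = 2.84e-07, adjusted p = 0.431 with an estimated correlation), again with a positive median over 7 refitted members under signal scaling. That gene was Slc1a3, which the astrocyte and radial glia lists both hold. The ribosomal protein genes, a list kept as a sign of RNA quality, moved with these groups and had 8 of 26 members lower and 23 when adjusted over the list alone (camera adjusted p = 3.72e-32, adjusted p = 0.105 with an estimated correlation), with a median of -0.489, and of 0.144 over 15 refitted members under signal scaling. Rpl8, for example, fell by 0.72 ± 0.117 (adjusted p = 0.00118), against 0.02 with signal scaling. Cholesterol synthesis genes had 1 of 20 lower both over all genes and when adjusted over the list alone (camera adjusted p = 0.00346, adjusted p = 0.511 with an estimated correlation). That gene was Hmgcs1, which makes the precursor of mevalonate (-0.68 ± 0.113, adjusted p = 0.0014). Glycolysis genes had 1 of 20 lower and 4 when adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.525 with an estimated correlation), and corepressor and heterochromatin genes 0 of 22 and 5 when adjusted over the list alone (camera adjusted p = 0.00337, adjusted p = 0.662 with an estimated correlation). Over 8, 9 and 6 refitted members the medians of these last 3 lists were also positive with signal scaling. None of the 20 pan-neuronal genes and none of the 23 GABAergic genes passed (camera adjusted p = 0.606 and 0.447).

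Outside the lists, Acsbg1, a fatty acid activating enzyme of glia, fell by 0.95 ± 0.121 (adjusted p = 2.35e-05) and Calr, a calcium-binding chaperone of the endoplasmic reticulum, fell by 0.88 ± 0.106 (adjusted p = 1.01e-05). Genes that rose besides the targets included Neu1, a lysosomal sialidase (3.07 ± 0.121, from 28.2 ± 4.45 to 232 ± 15.7 CPM), Tmem170 (2.63 ± 0.13), Mettl3, an RNA methyltransferase (2.14 ± 0.106), and Nfkbie, an inhibitor of NF-kappaB (1.43 ± 0.182), all with an adjusted p of 1.61e-05 or less. The markers of microglia, endothelium, choroid plexus, red blood cells and meninges had camera adjusted p-values of 0.606 to 0.998. The count of 155 genes depended on the libraries used. It was 30 without EGFP replicate 1, and 47, 425 and 61 without 3FOE replicates 1, 2 and 3, while the libraries of 21 July alone gave 50. Among the 3283 genes refitted with the background subtracted, 13 rose and 62 fell under TMM scaling, and 578 rose and 61 fell under signal scaling. Slc1a3, Hmgcs1, Rpl8 and Sox10 were not called without EGFP replicate 1, nor was Sox10 without 3FOE replicate 1 or 2. Their highest adjusted p over all alternatives without subtraction were 0.135, 0.0938, 0.0532 and 0.579.

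To ask the same of the ventral lineage, 3FOE was compared with EGFP in neurospheres of the ganglionic eminence (n = 3 each). Genes of inhibitory neurons such as Dlx1 rose, and genes of oligodendrocyte precursors and radial glia such as Olig2 and Fabp7 fell. Dlx1, a homeobox factor of ventral interneurons, rose from 73.1 ± 2.0 to 159 ± 8.63 CPM (log2 change 1.13 ± 0.0959, adjusted p = 9.02e-10), and Tubb3, the tubulin of young neurons, rose from 104 ± 12.7 to 205 ± 1.92 CPM (1.00 ± 0.139, adjusted p = 0.000241). Olig2 fell from 268 ± 13.1 to 102 ± 5.98 CPM (-1.36 ± 0.0973, adjusted p = 1.6e-11) and Fabp7 from 3600 ± 198 to 1800 ± 124 CPM (-1.01 ± 0.15, adjusted p = 0.00372). Over all genes, 363 rose and 2094 fell.

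**Figure D3:**
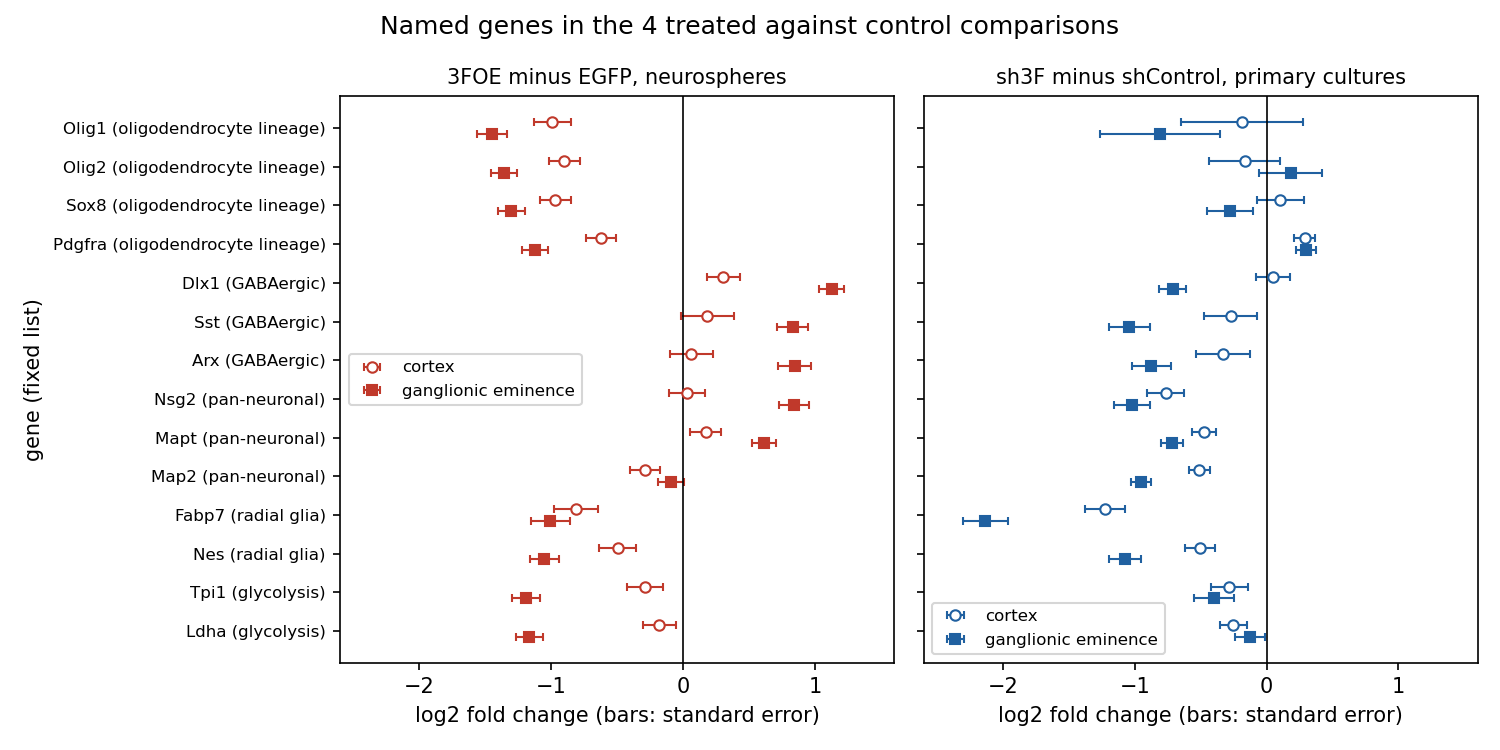
Log2 changes with their standard errors for 14 genes of the oligodendrocyte, inhibitory neuron, neuronal, radial glia and glycolysis groups in the 4 comparisons of treated with control libraries, with open circles for cortex and filled squares for ganglionic eminence. In the ganglionic eminence, Dlx1 lies at 1.13 with 3FOE and at -0.71 in cultures labelled sh3F, and Olig2 lies at -1.36 with 3FOE.

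In ganglionic eminence 3FOE neurospheres, of 23 GABAergic and ganglionic eminence genes, 10 rose over all genes and 11 when adjusted over the list alone (camera adjusted p = 2.17e-13, adjusted p = 0.029 with an estimated correlation). They included the neuropeptide genes Npy (1.70 ± 0.212, adjusted p = 1.16e-06) and Sst (0.83 ± 0.117, adjusted p = 7.9e-06) and the homeobox gene Arx (0.85 ± 0.122, adjusted p = 1.61e-05), while the abundant Dlx6 stood at 165 ± 11.9 against 158 ± 18.2 CPM (adjusted p = 0.608). Of 20 pan-neuronal genes, 9 rose, also when adjusted over the list alone (camera adjusted p = 2.12e-10, adjusted p = 0.125 with an estimated correlation). Examples were Nsg2, a vesicle protein of young neurons (0.84 ± 0.113, adjusted p = 2.38e-05), the calcium sensor Syt1 (0.82 ± 0.101, adjusted p = 9.48e-07) and the microtubule protein Mapt (0.61 ± 0.0942, adjusted p = 2.77e-05), whereas Map2 stood at 713 ± 42.4 against 741 ± 59.4 CPM (adjusted p = 0.675). Both groups had a positive median under both background-subtracted scalings, over 8 and 9 refitted members. Among striatal projection neuron genes, 2 of 19 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.000456, adjusted p = 0.0357 with an estimated correlation), among them Foxp1 (0.40 ± 0.098, adjusted p = 0.00652). Synapse genes had 6 of 26 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.00615, adjusted p = 0.168 with an estimated correlation). Among Cajal-Retzius and subplate genes, 1 of 16 rose, also when adjusted over the list alone (camera adjusted p = 0.0348, adjusted p = 0.283 with an estimated correlation), which was Reln, the secreted guide of cortical layering (0.45 ± 0.0921, adjusted p = 0.000983).

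Of 16 oligodendrocyte lineage genes, 14 fell, also when adjusted over the list alone (camera adjusted p = 1.1e-38, adjusted p = 0.0194 with an estimated correlation). Olig1 fell by 1.45 ± 0.113 (adjusted p = 6.96e-09) and Pdgfra, the growth factor receptor of oligodendrocyte precursors, by 1.12 ± 0.1 (adjusted p = 1.91e-08). Of 15 radial glia markers, 9 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.59e-10, adjusted p = 0.0532 with an estimated correlation). Vim (-1.04 ± 0.0886, adjusted p = 9.02e-10) and Nes, the progenitor filament gene (-1.05 ± 0.11, adjusted p = 9.58e-07), fell, while Sox1 rose by 0.70 ± 0.1 (adjusted p = 9.89e-06). Notch pathway genes had 8 of 17 lower and 10 when adjusted over the list alone (camera adjusted p = 7.38e-08, adjusted p = 0.0357 with an estimated correlation), among them Nrarp, a Notch feedback gene (-1.16 ± 0.137, adjusted p = 4.24e-07). Hedgehog and FGF target genes had 7 of 18 lower and 1 higher, and 8 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.01e-06, adjusted p = 0.029 with an estimated correlation). The FGF-induced Etv5 fell by 0.98 ± 0.103 (adjusted p = 5.46e-08) and Spry2, an inhibitor of that pathway, by 0.79 ± 0.128 (adjusted p = 5.42e-05).

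Glycolysis genes had 9 of 20 lower and 11 when adjusted over the list alone (camera adjusted p = 3.6e-21, adjusted p = 0.0194 with an estimated correlation), with Ldha, which makes lactate, going from 113 ± 16.2 to 52.8 ± 3.34 CPM (adjusted p = 1.17e-09). Ribosomal protein genes, a sign of RNA quality that moved with the falls above, had 24 of 26 lower and 25 when adjusted over the list alone (camera adjusted p = 1.42e-47, adjusted p = 0.029 with an estimated correlation), with a median of -0.734, and of -0.318 over 15 refitted members under signal scaling. Mitosis genes had 10 of 22 lower and 15 when adjusted over the list alone (camera adjusted p = 9.71e-07, adjusted p = 0.355 with an estimated correlation), for example the proliferation marker Mki67 (-0.81 ± 0.165, adjusted p = 0.0126). The stress response list had 6 of 21 lower and 8 when adjusted over the list alone (camera adjusted p = 7.54e-05, adjusted p = 0.0811 with an estimated correlation), including the chaperone Hspa5 (-0.72 ± 0.0888, adjusted p = 9.04e-07).

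Members of 5 further lists fell. These were corepressor and heterochromatin genes (9 of 22 lower, 10 when adjusted over the list alone, camera adjusted p = 9.71e-07, adjusted p = 0.207 with an estimated correlation), late progenitor genes (9 of 20, 10 when adjusted over the list alone, camera adjusted p = 2.7e-06, adjusted p = 0.283 with an estimated correlation) and mitochondrially encoded genes, another sign of RNA quality (6 of 13, 9 when adjusted over the list alone, camera adjusted p = 2.15e-05, adjusted p = 0.207 with an estimated correlation). The others were cholesterol synthesis genes (7 of 20, 10 when adjusted over the list alone, camera adjusted p = 0.000105, adjusted p = 0.125 with an estimated correlation) and astrocyte genes (7 of 18 lower and 2 higher, 8 and 2 when adjusted over the list alone, camera adjusted p = 0.0293, adjusted p = 0.446 with an estimated correlation). In the order given, 6, 10, 13, 8 and 7 members could be refitted, with medians of 0.065, 0.0762, 0.0168, 0.0549 and 0.199 under signal scaling, which moves all refitted genes by a median of 0.365. Under TMM scaling the last median was 0.12 and the others lay below 0. Rcor2, a subunit of a histone demethylase complex, fell by 0.67 ± 0.117 (adjusted p = 0.000148), and the proteoglycan gene Bcan by 1.04 ± 0.11 (adjusted p = 1.2e-06).

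Outside these groups, Gbp3, an interferon-induced GTPase, fell by 1.97 ± 0.162 (adjusted p = 5.33e-10), and Igfbp2, which binds insulin-like growth factors, from 121 to 44.4 CPM (adjusted p = 9.87e-10). Ugt8a, a myelin lipid enzyme outside the oligodendrocyte list, fell from 63.0 ± 16.3 to 22.3 ± 1.77 CPM (adjusted p = 0.00177). Neu1 rose by 3.06 ± 0.1, Tmem170 by 3.08 ± 0.111, Mettl3 by 2.37 ± 0.0908 and Nfkbie by 1.68 ± 0.143 (adjusted p of 9.02e-10 or less). Markers of the 5 other cell types had camera adjusted p-values of 0.325 to 0.619. The libraries of 16 July alone called 2468 genes. Among the 3283 genes refitted with the background subtracted, 201 rose and 116 fell under TMM scaling, and 72 rose and 35 fell under signal scaling. Dlx1, Sst, Tubb3, Nsg2, Mapt, Olig1, Olig2 and Pdgfra were called in the same directions under both scalings, Arx under neither, and Fabp7 under TMM scaling alone.

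Whether 3FOE acted differently in the 2 tissues was tested as the difference of both effects. Some glycolysis genes fell less in cortex, where Ldha stood at 45.0 CPM with 3FOE and 48.2 CPM with EGFP. For Ldha the difference was 0.99 ± 0.152 on the log2 scale (adjusted p = 0.00146). Of 20 glycolysis genes, 4 differed over all genes and 9 when adjusted over the list alone (camera adjusted p = 1.11e-13, adjusted p = 0.0458 with an estimated correlation). Etv5 (1.06 ± 0.159, adjusted p = 0.0014) and 5 of 18 Hedgehog and FGF target genes when adjusted over the list alone differed the same way (1 over all genes, camera adjusted p = 9.12e-07, adjusted p = 0.0458 with an estimated correlation).

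Some neuronal genes had the higher change in the ganglionic eminence. GABAergic genes differed in 1 of 23 cases over all genes, which was Dlx1 (-0.82 ± 0.15, adjusted p = 0.0109), and in 7 when adjusted over the list alone (camera adjusted p = 3.65e-09, adjusted p = 0.109 with an estimated correlation). Pan-neuronal genes differed in 2 of 20 cases and 7 when adjusted over the list alone (camera adjusted p = 4.04e-09, adjusted p = 0.199 with an estimated correlation). No oligodendrocyte lineage gene differed over all genes by edgeR, and 5 of 16 did when adjusted over the list alone (camera adjusted p = 9.98e-09, adjusted p = 0.199 with an estimated correlation), with the lower change in the ganglionic eminence. Of the 26682 genes tested, 28 had the higher change in cortex and 13 the lower. This count of 41 was 11 and 20 without cortical EGFP replicates 1 and 2, 17 without cortical 3FOE replicate 3, and 109 and 27 without ganglionic eminence EGFP replicates 2 and 3. It could not be repeated within a batch date, since each ganglionic eminence 3FOE library is of 16 July and each cortical EGFP library of 21 July. The background-subtracted splits were 2 higher and 12 lower (TMM scaling) and 9 higher and 11 lower (signal scaling). Of the 41 genes, 18 could be refitted this way, and 2 and 4 of these were called again.

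The EGFP neurospheres were compared between tissues as a check of the labels, with embryonic day and tissue differing together. Cortical neurospheres had more RNA of Neurod6 (0.99 ± 0.159 on the log2 scale, adjusted p = 8.65e-06) and Bhlhe22 (1.42 ± 0.293, adjusted p = 0.000291), transcription factors of cortical excitatory neurons, and of the astrocyte filament gene Gfap (83.8 ± 9.95 against 26.3 ± 6.34 CPM, adjusted p = 4.4e-07). Sst (-2.04 ± 0.186, adjusted p = 4.25e-10) and Dlx1 (-1.07 ± 0.134, adjusted p = 1.3e-07) were lower in cortex. These directions held for each gene that could be refitted under both background-subtracted scalings, which Bhlhe22 could not. Phf21b and Zfp57 were lower in cortex (-1.05 ± 0.173, adjusted p = 4.97e-05, and -0.99 ± 0.226, adjusted p = 0.00212). In all 2895 genes were higher and 5151 lower in cortex, against 891 and 375 with the background subtracted and TMM scaling and 1004 and 137 with signal scaling. Without ganglionic eminence EGFP replicate 3, 4094 genes were called. Meningeal markers, a list of another cell type, were higher in cortex in 5 of 16 cases and lower in 1 (camera adjusted p = 0.0354, adjusted p = 0.13 with an estimated correlation). Of the 18 lists called by camera, none was called with an estimated correlation (lowest adjusted p = 0.1). Of these 18, 16 could be tested again with the background subtracted, and none was called by camera. Within the 21 July libraries, where the ganglionic eminence group has a single library that is assumed to vary like the other groups, 900 genes were higher and 5117 lower in cortex. The 16 July libraries hold no cortical EGFP library.

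To see what changed when the factors were targeted, cultures labelled sh3F were compared with shControl in cortical primary cultures (n = 3 each), where a lowering of the targets themselves was not detected. Of 20 pan-neuronal genes, 3 fell over all genes tested (adjusted p = 0.28 with an estimated correlation). A small set of genes rose strongly. Map2, a dendritic microtubule protein, fell from 159 ± 22.6 to 116 ± 2.82 CPM (log2 change -0.51 ± 0.0793, adjusted p = 0.000122) and Fabp7 from 39.6 ± 7.06 to 18.3 ± 2.92 CPM (-1.23 ± 0.151, adjusted p = 1.43e-07). Neu1 rose from 21.2 ± 2.41 to 1500 ± 15.6 CPM (6.20 ± 0.0653, adjusted p = 5.03e-54). Altogether 110 genes rose and 159 fell.

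Pan-neuronal genes had 3 of 20 members lower over all genes and 12 when adjusted over the list alone (camera adjusted p = 4.16e-09, adjusted p = 0.28 with an estimated correlation), and the median of 6 refitted members was negative under both background-subtracted scalings. Mapt fell by 0.47 ± 0.0894 (adjusted p = 0.00126), and the abundant Dcx, a microtubule protein of migrating neurons, stood at 101 ± 4.16 against 115 ± 7.1 CPM (adjusted p = 0.223). Ribosomal protein genes, a sign of RNA quality, moved with them and had 3 of 26 lower and 17 when adjusted over the list alone (camera adjusted p = 2.17e-15, adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis genes had 3 of 20 lower and 5 when adjusted over the list alone (camera adjusted p = 8.42e-05, adjusted p = 0.28 with an estimated correlation), among them Hmgcs1 (-0.74 ± 0.122, adjusted p = 0.000177) and Fdps, which makes farnesyl pyrophosphate (-0.78 ± 0.158, adjusted p = 0.00326), and the median of 3 refitted members was positive with signal scaling. Idh1, an enzyme that supplies NADPH, fell by 1.06 ± 0.15 (adjusted p = 2.12e-05). Of 22 corepressor and heterochromatin genes, 2 fell, and 5 when adjusted over the list alone (camera adjusted p = 0.00161, adjusted p = 0.394 with an estimated correlation), including Cbx5, a heterochromatin protein (-0.49 ± 0.0921, adjusted p = 0.00134). Radial glia markers had 2 of 15 lower and 3 when adjusted over the list alone (camera adjusted p = 0.0385, adjusted p = 0.396 with an estimated correlation). Mitosis genes had 0 of 22 called by edgeR over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.000367, adjusted p = 0.28 with an estimated correlation), with 1 member refitted after subtraction, at a positive value.

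Among transcription factors, Bhlhe22 fell by 0.73 ± 0.171 (adjusted p = 0.0144) and Nr2f1, which patterns cortical areas, by 0.71 ± 0.145 (adjusted p = 0.00326), while Lhx5, a factor of Cajal-Retzius cell sources, rose from 21.2 ± 3.4 to 36.6 ± 6.64 CPM (0.88 ± 0.147, adjusted p = 0.000167). Besides Neu1, genes that rose included Tmem170 (5.23 ± 0.0724), Mettl3 (4.89 ± 0.0619, from 42.2 ± 4.2 to 1230 ± 37.6 CPM), Nfkbie (3.33 ± 0.114), Sez6 (3.12 ± 0.0683), Efna4 (2.50 ± 0.215) and Zbtb2 (2.34 ± 0.0914), with adjusted p of 1.46e-12 or less. Markers of the 5 other cell types had camera adjusted p-values of 0.268 to 0.794. The 269 calls became 95 and 592 without shControl replicates 1 and 2, and 136, 178 and 164 without sh3F replicates 1, 2 and 3, and the 16 July libraries alone gave 212. Among the 1297 genes refitted with the background subtracted, 20 were higher and 77 lower with TMM scaling, and 5 higher and 8 lower with signal scaling. Mapt, Fdps and Cbx5 were not called without shControl replicate 1. Their highest adjusted p over all alternatives without subtraction were 0.0825, 0.113 and 0.243.

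In ganglionic eminence cultures labelled sh3F (n = 3 against 3 shControl), where Phf21b RNA was lower, 10 of 20 pan-neuronal, 4 of 23 GABAergic and 5 of 22 paternally expressed imprinted genes fell (adjusted p = 0.0716, 0.194 and 0.0716 with an estimated correlation). Map2 went from 213 ± 19.7 to 114 ± 7.71 CPM (log2 change -0.95 ± 0.0781, adjusted p = 2.11e-11) and Dlx1 from 73.4 ± 0.6 to 44.9 ± 3.37 CPM (-0.71 ± 0.103, adjusted p = 2.41e-06). Fabp7 fell from 40.8 ± 4.4 to 9.82 ± 3.55 CPM (-2.13 ± 0.171, adjusted p = 8.73e-14). Over all genes 367 rose and 777 fell.

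Of 20 pan-neuronal genes, 10 fell and 12 when adjusted over the list alone (camera adjusted p = 6.29e-16, adjusted p = 0.0716 with an estimated correlation). Gap43, a growth cone protein, fell by 0.98 ± 0.129 (adjusted p = 8.32e-07), Mapt by 0.72 ± 0.0822 (adjusted p = 1.04e-08) and Nsg2 by 1.02 ± 0.138 (adjusted p = 0.00145), and the median of 6 refitted members was negative under both background-subtracted scalings. Gap43, Mapt, Nsg2 and the GABAergic gene Sst were called under TMM scaling and not under signal scaling (log2 changes of -0.45, -0.31, -0.51 and -0.48). GABAergic genes had 4 of 23 lower, and 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.194 with an estimated correlation). Beside Dlx1 these were Sst (-1.04 ± 0.154, adjusted p = 4.28e-06), Arx (-0.87 ± 0.148, adjusted p = 5.11e-05) and Lhx6, a factor of medial interneurons (-0.39 ± 0.0911, adjusted p = 0.00498), whose change became 0.18 with signal scaling. Radial glia markers had 6 of 15 lower, and 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.07e-08, adjusted p = 0.0716 with an estimated correlation), for example Nes (64.0 ± 6.58 to 31.6 ± 0.801 CPM, adjusted p = 3.62e-09).

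Imprinted genes were of interest because Zfp57 keeps methylation at their control regions. Their falls came with those of pan-neuronal genes, and a link to Zfp57, whose own call was often lost, was not tested. Of 22 paternally expressed imprinted genes, 5 fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.0716 with an estimated correlation). Peg3 fell by 0.65 ± 0.0792 (adjusted p = 4.27e-08), Ndn by 0.92 ± 0.134 (adjusted p = 2.87e-06) and Snrpn by 0.745 ± 0.13 (adjusted p = 9.03e-05). Of 17 maternally expressed imprinted genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.142, adjusted p = 0.427 with an estimated correlation). The paternally expressed Nnat went from 351 ± 29.2 to 120 ± 21.7 CPM (adjusted p = 0.00648). Corepressor and heterochromatin genes had 8 of 22 lower and 9 when adjusted over the list alone (camera adjusted p = 9.27e-07, adjusted p = 0.135 with an estimated correlation), among them the histone deacetylase gene Hdac2 (-0.77 ± 0.113, adjusted p = 4.35e-06) and the DNA methyltransferase gene Dnmt1 (-0.37 ± 0.0684, adjusted p = 0.000193).

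Signs of RNA quality moved with the neuronal and imprinted groups, and the estimated background was 85.4% against 76.6% of the counts of repeat-free coding genes. Ribosomal protein genes, a list of that kind, had 13 of 26 lower and 19 when adjusted over the list alone (camera adjusted p = 1.11e-20, adjusted p = 0.0847 with an estimated correlation). Mitochondrially encoded genes, another such list, had 6 of 13 lower and 8 when adjusted over the list alone (camera adjusted p = 3.9e-11, adjusted p = 0.0716 with an estimated correlation), with a median of 0.00165 over 12 refitted members under signal scaling. DNA replication genes had 3 of 22 lower and 6 when adjusted over the list alone (camera adjusted p = 0.000282, adjusted p = 0.0716 with an estimated correlation), including the sliding clamp Pcna (-1.01 ± 0.175, adjusted p = 8.58e-05). Mitosis genes had 3 of 22 lower and 5 when adjusted over the list alone (camera adjusted p = 0.0028, adjusted p = 0.199 with an estimated correlation), including Mki67 (-0.73 ± 0.113, adjusted p = 0.000151), and cholesterol synthesis genes 3 of 20 and 5 when adjusted over the list alone (camera adjusted p = 0.000934, adjusted p = 0.125 with an estimated correlation). Of the replication, mitosis and cholesterol lists only 3, 1 and 3 members could be refitted, too few to give the direction of the list. Hist1h1b, a linker histone, fell by 1.84 ± 0.23 (adjusted p = 1.17e-07).

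Some genes rose in ganglionic eminence cultures labelled sh3F. Pdgfra rose from 102 ± 3.37 to 123 ± 4.27 CPM (0.30 ± 0.0756, adjusted p = 0.0103), a call lost with DESeq2 and without shControl replicate 3 or sh3F replicate 1 (adjusted p up to 0.0758). It was also the only called member of 15 meningeal markers, a list of another cell type (also when adjusted over the list alone, camera adjusted p = 0.00487, adjusted p = 0.0716 with an estimated correlation), while the markers of the other 4 cell types had adjusted p-values of 0.351 to 0.966. Lhx5 rose by 0.67 ± 0.148 (adjusted p = 0.00238) and Nfia, a factor of the switch to glia, by 0.36 ± 0.0878 (adjusted p = 0.00626). Neu1 rose by 6.21 ± 0.0634, Tmem170 by 5.64 ± 0.0734, Mettl3 by 5.31 ± 0.0623, Nfkbie by 3.70 ± 0.11 and Sez6 by 3.60 ± 0.0679 (adjusted p of 2.18e-32 or less). The 1144 calls became 596 without shControl replicate 1 and 677 and 717 without sh3F replicates 1 and 3, and the 16 July libraries alone gave 882. Among the 1297 genes refitted with the background subtracted, 81 were higher and 226 lower with TMM scaling, and 192 higher and 22 lower with signal scaling.

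The difference between the tissues in the response to sh3F passed for 8 genes in each direction. Dlx1 (0.765 ± 0.156, adjusted p = 0.0254) and Peg3 (0.60 ± 0.108, adjusted p = 0.00723) fell in the ganglionic eminence and stood at 27.1 against 26.0 and 80.3 against 81.1 CPM in cortex. Bhlhe22 went the other way (-1.47 ± 0.307, adjusted p = 0.0318). Mitochondrially encoded genes differed in 2 of 13 cases and 4 when adjusted over the list alone (camera adjusted p = 4.45e-13, adjusted p = 0.111 with an estimated correlation), GABAergic genes in 1 of 23 and 3 (camera adjusted p = 2.96e-05, adjusted p = 0.153 with an estimated correlation) and radial glia markers in 1 of 15 and 4 (camera adjusted p = 6.3e-05, adjusted p = 0.175 with an estimated correlation). With shControl replicates left out, the 16 calls became 57 and 10 (cortical replicates 1 and 3) and 5 and 6 (ganglionic eminence replicates 1 and 3). With sh3F replicates left out they became 6 and 8 (cortical replicates 2 and 3) and 10 and 10 (ganglionic eminence replicates 1 and 2). The 16 July libraries gave 11, DESeq2 gave 2, and edgeR with the background subtracted, where 3 of the 16 genes could be refitted, gave 0 (83 genes at an unadjusted p under 0.05 with TMM scaling and 79 with signal scaling).

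The shControl cultures of both tissues, taken at the same embryonic day, were compared as a check of the region labels. GABAergic genes were lower in cortex in 9 of 23 cases, and in 13 when adjusted over the list alone (camera adjusted p = 3.84e-49, adjusted p = 0.000433 with an estimated correlation), among them Dlx1 (-1.49 ± 0.1, adjusted p = 1.07e-15) and Arx (-1.79 ± 0.147, adjusted p = 1.31e-12). Cortical excitatory identity genes were higher in cortex in 6 of 15 cases and 7 when adjusted over the list alone (camera adjusted p = 5.51e-14, adjusted p = 0.0194 with an estimated correlation), with Bhlhe22 at 26.7 ± 7.56 against 4.17 ± 0.699 CPM (adjusted p = 4.91e-14) and the proneural gene Neurog2 at 14.4 ± 2.1 against 4.07 ± 0.326 CPM (adjusted p = 7.94e-07). Paternally expressed imprinted genes were lower in cortex in 6 of 22 cases and 7 when adjusted over the list alone (camera adjusted p = 1.03e-17, adjusted p = 0.000618 with an estimated correlation), including Ndn (-1.30 ± 0.126, adjusted p = 2.13e-10) and Peg10 (-1.16 ± 0.116, adjusted p = 7.17e-10). Pan-neuronal genes were lower in 8 of 20 cases and 9 when adjusted over the list alone (camera adjusted p = 1.75e-22, adjusted p = 0.0194 with an estimated correlation), for example Mapt (-0.67 ± 0.0749, adjusted p = 8.73e-09). Zbtb18, a repressor needed in cortical neurons, was higher in cortex by 1.04 ± 0.101 (adjusted p = 5.26e-10). Markers of microglia, endothelium, choroid plexus, red blood cells and meninges had camera adjusted p-values of 0.524 to 0.732. In all 40 genes were higher and 197 lower in cortex, and the 16 July libraries gave 120 calls. The count was 149 and 123 without cortical replicates 2 and 3 and 115, 124 and 118 without ganglionic eminence replicates 1, 2 and 3. Of the genes refitted with the background subtracted, 4 were higher and 29 lower with TMM scaling, and 555 higher and 5 lower with signal scaling.

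Overexpression and knockdown were then set side by side. In the ganglionic eminence, 41 genes rose with 3FOE and fell in cultures labelled sh3F, where independent lists would share 11 (Fisher's exact test, adjusted p = 1.13e-12). They included Dlx1, Sst, Arx, Mapt, Nsg2, Dcx, Dpysl5, Kif5c and Phf21b itself. Another 9 genes fell with 3FOE and rose in cultures labelled sh3F, fewer than the 29.6 of independent lists (adjusted p = 1.16e-05), among them Pdgfra and Cspg4, both of oligodendrocyte precursors. The 356 genes that fell in both, against 63.7 for independent lists (adjusted p = 3.41e-181), included Nes, the creatine kinase gene Ckb and the ribosomal protein gene Rplp2. Of these 356, 111 could be refitted with the background subtracted and TMM scaling, and 16 were called lower in both again. Of the 41, the 9 and the 24 that rose in both, 15, 1 and 3 could be refitted, and all were called again. That scaling raises the refitted changes with 3FOE by a median of 0.268, which favours rises over falls. These shares therefore do not rank the sets. Those 24, against 5.11 for independent lists, included Neu1 and Mettl3 (adjusted p = 8.27e-10), and 14 were left without genes that match an Alu sequence. Across genes, which are not independent replicates, the log2 changes had a Spearman correlation of 0.201 (0.442 with the background subtracted). With 1 library left out, the 356 became 192 to 390. The 41 became 22 to 35 in such fits. The 9 became 3 to 11 with 1 library left out.

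In cortex, 15 genes fell in both, against 0.857 for independent lists (adjusted p = 2.42e-14), among them Hmgcs1 and Hsp90b1, a chaperone of the endoplasmic reticulum. Their number was 9 without the batch term and 1 without EGFP replicate 1. It was 3, 51 and 7 without 3FOE replicates 1, 2 and 3, 1 and 46 without shControl replicates 1 and 2, and 3 without sh3F replicate 1. With the background subtracted and TMM scaling, 9 of the 15 could be refitted and 0 were called again in both by edgeR. Neu1, Mettl3, Tmem170, Sez6, Nfkbie and Zbtb2 rose in both, against 0.0542 (adjusted p = 1.53e-11), and 0 genes were called in opposite directions by edgeR, against 0.0814 and 0.572 for independent lists. With TMM scaling after subtraction, 3 of 1236 refitted genes rose with 3FOE and fell in cultures labelled sh3F. They were Map1b, Tubb3 and Stmn1, named after their values were seen, and none fell and then rose by edgeR. The correlation across genes was 0.1 (0.219 with the background subtracted), and it was 0.0518 without shControl replicate 1 and 0.0631 without 3FOE replicate 1.

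Between the tissues, 3FOE lowered 120 genes in both, against 11.1 (adjusted p = 4.24e-110), including Sox8, Olig2, Calr and Glul, which makes glutamine, and raised 11 in both, against 0.19 (adjusted p = 2.85e-18), the 3 targets and the tubulin regulator Stmn1 among them. Cultures labelled sh3F had 123 genes lower in both tissues, against 4.82 (adjusted p = 1.6e-155), including Fabp7, Map2, the axon guidance gene Dpysl2 and the histone gene H3f3a, and 86 higher in both, against 1.57 (adjusted p = 2.33e-139). The correlations across genes were 0.303 for 3FOE and 0.3 for sh3F. The 120 became 12 without cortical EGFP replicate 1, and 28, 320 and 44 without cortical 3FOE replicates 1, 2 and 3. The 123 became 27 and 331 without cortical shControl replicates 1 and 2, and 42 and 68 without cortical sh3F replicates 1 and 3. The 86 became 51 without cortical shControl replicate 1. With the background subtracted and TMM scaling, 82 of the 120 shared falls with 3FOE could be refitted and 11 were called again. Of the 123 with sh3F, 52 could be refitted and 44 were called again.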

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

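The tests of Alu matches, of an opposite response, of the batch date and background reads in the knockdown, and of background reads in the ganglionic eminence 3FOE neurospheres were chosen only after the result was seen. Those of repeats in general, of the batch date in these neurospheres and of other splits were not, but the reading of the tissue-difference splits was. The results here are differences between the tissues in the response to the same treatment, found by a test of the difference itself.

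The measured log2 change with 3FOE differed between cortex and ganglionic eminence for 41 genes. Of these, 18 could be refitted with the background subtracted, of which 2 (TMM scaling) and 4 (signal scaling) were called again, and the count ran from 11 to 109 with 1 library left out. On the log2 scale, with cortex minus ganglionic eminence, the change in Zfp7 differed by -1.18 (adjusted p = 0.00386), so this factor was raised less in cortex. Higher changes in cortex were found for Gbp3 (1.81), Igfbp3 (1.48), Peg12 (1.42), Rhoq (1.13), Acadl (1.11), Etv5 (1.06), Fbln2 (1.03) and A2m (1.02), and for the glycolysis genes Ldha (0.99), Tpi1 (0.90), Pfkl (0.71) and Pgk1 (0.64). Lower changes in cortex were found for Rdh19 (-1.18), Sox1 (-0.90), Dlx1 (-0.82), Nsg2 (-0.81), Rnd3 (-0.78), Chl1 (-0.71) and Syt1 (-0.71).

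The response to sh3F differed between the tissues for 16 genes. Higher changes in cortex were found for Hap1 (1.25), Ddah1 (0.88), Dlx1 (0.765), mt-Nd2 (0.76), Peg3 (0.60) and mt-Nd5 (0.57), and lower ones for Btbd35f18 (-2.66), Bhlhe22 (-1.47), Mro (-0.765), Zbtb18 (-0.72), Sez6 (-0.48), Aqr (-0.47) and Mettl3 (-0.42). Of 100 splits drawn from 200, 9 gave as many genes, the real one included. The highest other count, 1440, came from all cortical shControl with all ganglionic eminence sh3F libraries, the sum of both sh3F effects. All 8 other splits with as many genes kept those sh3F libraries together and hold their whole effect, as do 6 splits that called 2 to 6 genes. The 85 that mixed these libraries called at most 5, with that effect in their spread. None of these are chance values for a tissue difference, so the splits do not show whether chance can be excluded.

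A set of genes was higher in both 3FOE and sh3F libraries of both tissues, namely Neu1, Mettl3, Tmem170, Sez6, Nfkbie and Zbtb2, while treated cultures received 3 vectors and controls 1. A rise of repeat-rich genes as a whole is argued against, since the tenth of genes richest in repeats had a median log2 change of 0.033 in cortical sh3F cultures. That median, over 2552 genes, cannot show whether repeats raised these 6 genes. The 6 of 11 genes higher in both 3FOE comparisons that were also higher in both sh3F comparisons restate how the set was chosen and decide nothing about a response to the factors. Reads from another organism that match Alu-type repeats may contribute, since 5 of these 6 genes match an Alu consensus, against 5.94% of 25402 other genes (Fisher's exact test, two-sided, p = 4.26e-06). This stays open because the idea came from these genes, because the 1514 matching genes as a set had a median change of 0.0209, because mouse B1 repeats share ancestry with Alu, and because how to read the test was settled after its value was seen. Sequences carried by the vectors, RNA carried over with virus and a response to a higher vector dose were not analysed here and stay open as well.

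Of 1297 expressed genes, 224 were called lower and 29 higher in ganglionic eminence cultures labelled sh3F, while the median log2 change over all 1297 was -0.0253 (0.0534 and 0.664 with the background subtracted and TMM or signal scaling). The batch date is argued against as the whole cause, since the 16 July libraries alone called 191 expressed genes lower and 21 higher, against 224 lower over both dates. Those 224 had a median of -0.745 in the 16 July libraries, the test planned first, but their choice favours a negative value. A larger share of background reads in sh3F libraries stays open: 88.4% of the 224 were still called lower with the background subtracted and TMM scaling, and 8.48% with signal scaling, but that scaling raises the refitted genes together by a median of 0.696, so the loss follows from it and is no evidence. A biological effect of the vectors stays open and untested.

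In ganglionic eminence 3FOE neurospheres 9 of 20 pan-neuronal genes were higher and 14 of 16 oligodendrocyte lineage genes lower (adjusted p = 0.125 and 0.0194 with an estimated correlation). The share of background reads is argued against as the whole cause, since the pan-neuronal median (0.993 over 9 genes) lay 2.06 above the oligodendrocyte median (-1.07 over 10 genes) with the background subtracted and TMM scaling, and 2.07 above it with signal scaling. The batch date is argued against too, with a difference of 1.55 among the 16 July libraries (medians of 0.325 and -1.23). A response to the 3 factors, a change in which cells grew in the neurospheres and an effect of the number of vectors stay open, and these data do not separate them.

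Other splits of the 6 libraries are too few for a share under 0.05 in the comparisons of 3 against 3 libraries, where 1 of 10 splits, the real one, gave as many genes in each. The real and the highest other counts were 2457 and 1 for 3FOE in the ganglionic eminence, 269 and 1 for sh3F in cortex, 1144 and 2 for sh3F in the ganglionic eminence, and 237 and 65 between the shControl groups. Of the shControl splits, 4 put both 21 July libraries on one side and called 1, 3, 8 and 65 genes, and the 16 July libraries alone gave 120.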

How the results depend on the processing

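The background-subtracted fits, the removal of genes matching an Alu sequence, the 21 July fit between EGFP groups and the overlaps with 1 library left out were chosen only after the data were seen, and the other alternatives before. Over 328 results for single genes and 4666 alternative values, 3943 kept their side of the threshold and, but for 3 uncalled values of Phf21b, the direction. Another 698 kept the direction but were no longer called, 1 became called and 24 reversed. Without background subtraction, 0 of the 4336 values reversed a called change by edgeR or DESeq2 and 564 lost the call. Outside these values, the uncalled changes of Zfp57 in cortical sh3F cultures and of Zfp7 in those of the ganglionic eminence did change sign with 1 library left out. Over 94 results for gene lists, 308 of 514 values kept both, 194 lost the call and 12 reversed. Where a value changed, the cause was not tested, except that fits with fewer libraries or genes have less power. The depth of the knockdown libraries, of which a large share was background, limits what can be said of transcripts near it, the targets included.

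With the background subtracted, counts were 75 (TMM scaling) and 639 (signal scaling) for 3FOE in cortex, 317 and 107 for 3FOE in the ganglionic eminence, 1266 and 1141 between EGFP groups, 14 and 20 for the tissue difference in 3FOE, 97 and 13 for sh3F in cortex, 307 and 214 for sh3F in the ganglionic eminence, 33 and 560 between shControl groups, and 0 and 0 for the tissue difference in sh3F by edgeR (83 and 79 at an unadjusted p under 0.05, against 2 calls with DESeq2). DESeq2 gave 238 for 3FOE in cortex, 172 and 635 for sh3F in cortex and ganglionic eminence, and 90 between shControl groups. Fitting only the groups compared gave 46 for 3FOE and 162 for sh3F in cortex. Single batch dates gave 50 for 3FOE in cortex, 120 between shControl groups and 6017 between EGFP groups (21 July), and no filter gave 78 for the tissue difference in 3FOE (66 higher, 12 lower), against 41.

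Leaving out each library in turn gave 30 to 425 calls for 3FOE in cortex, 1756 to 2528 in the ganglionic eminence, 4094 to 7610 between EGFP groups, 11 to 109 for the tissue difference in 3FOE, 95 to 592 for sh3F in cortex, 596 to 982 in the ganglionic eminence, 115 to 339 between shControl groups and 5 to 57 for the tissue difference in sh3F. Where this left 1 cortical EGFP library, that library was assumed to vary like the other groups. Log2 changes with 3FOE in cortex and ganglionic eminence were 3.44 to 3.88 and 3.68 to 3.93 for Phf21b, 3.05 to 3.26 and 4.17 to 4.42 for Zfp7, and 4.05 to 4.29 and 4.71 to 5.00 for Zfp57. With sh3F they were -0.57 to -0.24 and -0.87 to -0.65 for Phf21b, -0.18 to -0.0086 and -0.043 to 0.22 for Zfp7, and -0.41 to 0.032 and -0.73 to -0.49 for Zfp57. The fall of Zfp57 in the ganglionic eminence was not called with DESeq2 (-0.61, adjusted p = 0.21) or within the 16 July libraries (-0.59, adjusted p = 0.0788).

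With signal scaling the log2 changes below reversed. That scaling moves the refitted genes together, by medians of 0.617, 1.12, 0.696 and 0.745 for the 4 comparisons in the order given, so these reversals are no evidence about single genes. For 3FOE in cortex they were Rpl8 (0.0237), Rplp0 (0.26), Rpl13 (0.14), Pdgfra (0.0048), Vim (0.0277), Bcan (0.0061), Hsp90b1 (0.13), Rpl22 (0.0427), Rplp2 (0.18), Rpl35 (0.17), Pea15a (0.198) and Ckb (0.23). Between EGFP groups they were Hdac2 (0.000798), mt-Nd5 (0.57, and 0.30 with TMM scaling), mt-Nd1 (0.16) and mt-Atp8 (0.22). For sh3F in the ganglionic eminence they were mt-Nd2 (0.11), mt-Nd4 (0.17) and mt-Nd5 (0.35), and between shControl groups mt-Nd4 (0.34) and mt-Nd5 (0.44). The tissue difference of Zfp57 in 3FOE became 7.57 and 8.09 with TMM and signal scaling, from -0.76 (adjusted p = 0.349). Its counts in cortical EGFP libraries, 53 and 63, lie below the background estimates of 77.2 and 82.8, so these sizes are set by a control at 0 and cannot be read as folds.

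Lists with under 3 refitted members could not be tested with the background subtracted, which left 25 of 38 in neurospheres and 9 of 38 in primary cultures. Of the called lists, 8 of 8 could be tested again for 3FOE in cortex (3 were called again with TMM scaling), 16 of 18 in the ganglionic eminence (8), 16 of 18 between EGFP groups (0) and 11 of 13 for the tissue difference in 3FOE (6). For sh3F these were 3 of 6 in cortex (2) and 6 of 11 in the ganglionic eminence (3), with 4 of 12 between shControl groups (3) and 5 of 8 for the tissue difference in sh3F (3). Lower counts after subtraction are thus in part lists that were not tested. The number of lists called went from 8 for 3FOE in cortex to 5 (TMM scaling), 4 (signal scaling), 0 (estimated correlation) and 0 (fry). It went from 18 for 3FOE in the ganglionic eminence to 8, 8 and 7 (estimated correlation). Between EGFP groups 18 became 0, 0, 0 and, with fry, 35. For the tissue difference in 3FOE 13 became 7, 6, 2 and 2 in the same order. For sh3F, 6 in cortex became 2, 2, 0 and 0, and 11 in the ganglionic eminence became 3, 3 and 0. Between shControl groups 12 became 3, 3, 7 and 7, and for the tissue difference in sh3F 8 became 3, 3, 0 and 0. Lists that reversed, with camera's adjusted p under TMM and signal scaling, were astrocyte genes for 3FOE in the ganglionic eminence (0.454 and 0.356), late progenitor genes (0.363 and 0.23) and astrocyte genes (0.185 and 0.16) between EGFP groups, Notch genes for the tissue difference in 3FOE (0.861 and 0.718) and synapse genes between shControl groups (0.635 and 0.62). Corepressor genes reversed with TMM scaling for the tissue difference in 3FOE (0.969), and maternally expressed imprinted genes with signal scaling between EGFP groups (0.961).

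For the overlaps, leaving out the batch term gave 9 genes lower in both treatments in cortex, 15 lower with 3FOE and higher with sh3F in the ganglionic eminence, 64 lower with sh3F in both tissues and correlations between tissues of 0.248 (3FOE) and 0.223 (sh3F). Genes of at least 5 CPM gave correlations of 0.126 and 0.27 between treatments in cortex and ganglionic eminence, and of 0.38 and 0.36 between tissues. With the background subtracted the correlations were 0.219, 0.442, 0.529 and 0.648, and the counts in cortex were 2 higher and 0 lower in both treatments by edgeR, and 3 higher with 3FOE and lower with sh3F. In the ganglionic eminence 21 were lower in both treatments and 1 moved from lower to higher. Between tissues 16 were lower in both with 3FOE, and 73 lower and 14 higher in both with sh3F. Without genes matching an Alu sequence, 1 gene was higher in both treatments in cortex, 14 in the ganglionic eminence and 5 with 3FOE in both tissues. With 1 library left out, the correlations were 0.0518 to 0.126 and 0.172 to 0.204 between treatments in cortex and ganglionic eminence, and 0.23 to 0.324 (3FOE) and 0.225 to 0.304 (sh3F) between tissues. Genes lower in both treatments were 1 to 51 in cortex and 192 to 390 in the ganglionic eminence, where 22 to 35 were higher then lower, 3 to 11 lower then higher and 17 to 26 higher in both. Between tissues 12 to 320 were lower and 8 to 11 higher in both with 3FOE, and 27 to 331 lower and 51 to 84 higher in both with sh3F.

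Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at -0.269 to 0.0541. A replicate block gave 45 calls for 3FOE in cortex, 26 for the tissue difference in 3FOE, 3 genes lower in both treatments in cortex, 237 lower in both and 26 higher then lower in the ganglionic eminence, 29 and 80 lower in both tissues with 3FOE and sh3F, and a correlation between tissues of 0.272 for 3FOE. With the block, Zfp57 in ganglionic eminence sh3F had a log2 change of -0.595 (adjusted p = 0.0639).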

Other observations

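The values with the background subtracted were chosen only after the data were seen, and the other tests before. In shControl cultures, 3 of 16 upper-layer neuron genes were higher in cortex than in the ganglionic eminence, and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0318, adjusted p = 0.332 with an estimated correlation). Satb2, a chromatin factor of callosal neurons, was higher in cortex by 0.46 on the log2 scale (adjusted p = 0.0186). Cholinergic neuron genes were lower in cortex in 2 of 14 cases and 4 when adjusted over the list alone (camera adjusted p = 9.94e-06, adjusted p = 0.0194 with an estimated correlation). Striatal projection neuron genes were lower in 2 of 19 cases and 4 when adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.0167 with an estimated correlation), of which 1 member could be refitted with the background subtracted. Nfib, a factor of late progenitors, was higher in cortex by 1.01 (adjusted p = 1.34e-09).

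In EGFP neurospheres, 13 of 15 radial glia markers were lower and 1 higher in cortex than in the ganglionic eminence, also when adjusted over the list alone (camera adjusted p = 6.87e-11, adjusted p = 0.1 with an estimated correlation). Nes stood at 71.1 against 348 CPM (log2 difference -2.22 ± 0.147, adjusted p = 1.55e-10), and Sox2, a core factor of neural stem cells, differed by -1.87 ± 0.148 (adjusted p = 1.01e-09). After subtraction of the background, the differences were -1.44 and -0.71 with TMM scaling and -1.17 and -0.44 with signal scaling, where Sox2 was not called (adjusted p = 0.11).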
